A study of Arabidopsis thaliana with 28 samples.

How the data were processed

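The samples were 28 libraries from RNA of wild-type Arabidopsis seedlings, 2 libraries for each of 7 times with ABA and 7 times with ethanol mock, per the labels. Per the submitters' processing notes, reads were checked with FastQC and mapped with STAR to the TAIR10 genome. The versions of these tools, the counter, the miRNA annotation, the handling of reads that map to several loci, the normalization and the test of the authors are not given in the sources used here. The study's design text gives more samples than the 28 in the labels, and only these 28 were used. The deposited table had 421 mature miRNAs with 14 columns of group signal and 14 columns of the authors' comparisons. Per the file headers, each signal column holds 1 treatment at 1 time, where single libraries had been assumed before the data were examined. The 7 deposited log2 ratio columns equal the log2 of the ABA mean over the mock mean. The other 7 columns hold an adjusted p-value of the authors for each time.

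Each deposited signal value was found to be a sum of whole multiples of 2 steps per column, the form that the mean of 2 counts divided by their size factors takes. The steps were estimated from the low values and gave size factors of 0.687 to 1.36, close to median-of-ratios factors of the 4 libraries of each time, so each time had been scaled separately. With these steps 100% of values between 0 and 100 in each column had a split, and with steps moved at random by up to 10% a mean of 0% had. A value was split into 2 library values where only 1 pair of whole counts fitted, which held for 5293 of 5894 values (89.8%). For 61 abundant miRNAs at least 1 group could not be split. In each group the library with the larger size factor is called a and the other b, and they carry no replicate number, so libraries could not be matched between groups.

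The log2 of each library value plus a pseudocount of 1 was fitted with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, with 1 mean for each of 14 groups and 14 residual degrees of freedom. Tested miRNAs had a value of at least 1 in at least 2 libraries. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. The contrasts were the mean of the 7 ABA minus mock differences, the difference at each time, the mean difference at the 4 late times minus that at the 3 early times, F tests of the interaction and F tests of the time course in each treatment. The time courses used size factors computed over all 28 libraries by the median of ratios, since the authors' scaling does not carry across times. The 17 miRNA lists were tested with camera of limma with an estimated correlation between members, and 16 had enough tested members. The comparisons, tests, lists and naming rule were fixed before the data were examined, with a choice of test for each kind of values.

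The naming rule took, for the mean contrast, the 12 raised and the 12 lowered miRNAs with the largest log2 change among called miRNAs whose effect had the same sign at 6 or more times. For each time it took the 3 raised and the 3 lowered with the largest change among called miRNAs whose 2 ABA libraries both lay above or both below the mock libraries. It took the 5 called with the smallest p for late minus early and for the interaction, and the 8 with the smallest p in each time course. The miR159, miR168, miR169, miR393, miR394 and miR402 families were always named, list members could be named as examples, and mature sequences shared by loci are given as uncertain between them. Positions are on RefSeq TAIR10.1, in which 414 of 421 names were matched by name to 336 distinct sequences, and 45 sequences were shared by 123 miRNAs. The authors mapped to TAIR10, and the miRNAs were joined to TAIR10.1 by name, with no position carried from 1 build to the other.

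Tested on simulated data with 2 libraries a group, the split gave 1 pair for 5312 of 5894 values, and 0 of these were wrong. The simulation gave every group the same biological coefficient of variation, 0.2. For the mean contrast, with 354 simulated miRNAs, 64.5% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold were called, and 2.02% of the unchanged ones. At a single time fewer were called: for 3 h, with 365 miRNAs, 19.4% of those changed 1.5-fold, 46.2% of those changed 2-fold and 86.7% of those changed 4-fold. For 12 h, with 359 miRNAs, 12.9% of those changed 1.5-fold, 57.7% of those changed 2-fold and 100% of those changed 4-fold were called. In the real data the SD of the log2 difference between libraries was 0.60 in mock and 0.49 in ABA at 3 h. At 12 h it was 0.21 and 0.24. The simulated rates of these single times therefore do not carry over to the real ones. For the interaction, with 354 miRNAs, 85.7% of those changed 4-fold at the late times only were called, and late minus early called 90.5% of these. The camera test called the raised list of 15 and not the unchanged list of 15.

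The alternatives were quantile normalization, centring each library on its median, no filter, a mean of at least 10, a pseudocount of 0.1, only the 4 libraries of a time, a preset correlation of 0.01 for the lists and leaving out 1 library. Chosen after seeing the data were the other scaling across times, 1 miRNA for each mature sequence, leaving out 1 time, the authors' deposited p-value as the call and a limma fit of the 7 log2 ratios of deposited means. The last 2 also cover abundant miRNAs without library values. A replicate block and count models had been foreseen and were not run, since the table gives neither replicate numbers nor all counts. Correlations were tested by permutation, exactly for the number of calls over the 7 times, with 10000 permutations for effects between times, and with 100000 for the arms and GC content. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest. Targets of the miRNAs were not analysed here.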

Results

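Mature miRNAs were profiled in wild-type Col-0 seedlings of Arabidopsis thaliana given abscisic acid (ABA), the hormone of drought response and seed dormancy, or the ethanol mock. Seedlings were collected 0.5, 1, 3, 6, 9, 12 and 24 h after the start, with 2 libraries in each of 14 groups and 28 libraries in all. The dose of ABA was not given in the sources used here. The authors' deposited table listed 421 miRNAs, each with a mean normalised read count for every group. The group totals of the authors' deposited table lay between 4305799.9 for mock at 6 h and 7644818 for ABA at 1 h. The largest single entry of a group was miR393a-5p, miR393b-5p or miR159a, with 7.55% to 19.7% of the group total. The miR393-5p sequence is listed at both loci with nearly equal values, so this share is that of 1 entry and not of the sequence. The 2 library values behind each mean were recovered for 360 miRNAs in all 28 libraries. The other 61 miRNAs had a mean over groups of at least 3331, so the most abundant ones lack library values. The recovered counts summed to 218054 to 740594 for a library. The miRNAs split in a group held 3.57% to 13.5% of its total of normalised means, and the full depth of a library is unknown. The SD of the log2 difference between the 2 libraries of a group ran from 0.21 in mock at 12 h to 0.6 in mock at 3 h. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

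The first comparison asked which miRNAs ABA changed as a mean over the times, by the mean of the 7 ABA minus mock differences (14 libraries for each treatment). Among the raised miRNAs were members of the copper and phosphate lists, although neither list passed the limma camera test as a set (adjusted p = 0.0857 each). The level of miR397a, which targets laccases, was 3.73-fold higher (log2 difference 1.90, SE 0.10, adjusted p = 3.09e-12). The levels of miR2111b-3p and miR399d, both known from the response to low phosphate, were 2.98-fold and 3.42-fold higher, with log2 differences of 1.58 (SE 0.08) and 1.78 (SE 0.17). On the lowered side, miR169b-5p, which targets NF-YA transcription factor subunits, was 2.26-fold lower (log2 difference -1.17, SE 0.09, adjusted p = 2.19e-09), and miR864-5p was 2.68-fold lower (log2 difference -1.42, SE 0.15, adjusted p = 2.35e-07).

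Of 355 tested miRNAs, 166 passed the limma test at an adjusted p under 0.05, 79 raised and 87 lowered, and they held 130 distinct mature sequences, 56 raised and 74 lowered. Median centring gave 82 raised and 81 lowered, and leaving out mock library a of 3 h gave 85 and 80, so neither direction prevailed. Folds and log2 differences here are on the log2(value + 1) scale. The largest rise was that of miR826a at 2.42 (SE 0.25, adjusted p = 1.62e-07), a miRNA with low counts that the authors' deposited table lists at 0 in mock at 0.5, 3 and 12 h. The related miR826b rose by 1.52 (SE 0.28). The sizes for miR826a and miR826b depend on the pseudocount, and with 0.1 they were 4.34 and 3.10. The same 5p sequence of MIR2111a and MIR2111b rose by 1.55, and its reads cannot be assigned to 1 locus. Further raised miRNAs were miR857 at 1.30, miR399e at 1.22, miR398a-3p at 1.13 and the sequence shared by miR398b-3p and miR398c-3p at 1.14. Behind miR864-5p, the largest falls were those of miR5634 at -1.29, miR167a-3p at -1.20, miR169b-3p at -1.19, miR773b-5p at -1.09 and miR868-5p at -1.08. The levels of miR4221, miR169g-5p, miR393a-3p and miR847 fell by 0.89, 0.84, 0.81 and 0.80. The fall of miR869 at -0.84 (SE 0.34, adjusted p = 0.0447) lost its call under 6 of the other settings and in 20 of 28 fits with 1 library left out, at -0.55 without ABA library b of 24 h and -0.86 to -0.69 in the other 19. It kept the call without mock library b of 1 or 3 h, ABA library a of 1, 3, 12 or 24 h, or ABA library b of 0.5 or 9 h. By the naming rule, all miRNAs named so far for this contrast had the same sign at 6 or 7 of the 7 times.

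The recovered library values of miR397a give the size of the response against the mock background. At 6 h the mean normalised read count was 3475 ± 1129 in ABA and 640.1 ± 79.5 in mock (SD, n = 2 libraries each), and at 24 h it was 1596 ± 55.7 against 473 ± 25. For miR169b-5p the values at 12 h were 2387 ± 123 in ABA and 9055 ± 59.5 in mock (SD, n = 2). On the RefSeq TAIR10.1 assembly the mature miR397a lies on chromosome 4, 2625960 to 2625980, plus strand, within MIR397a and opposite to the coding gene ENT6. The mature miR2111b-3p lies on chromosome 5, 400464 to 400484, plus strand, miR399d on chromosome 2, 14442988 to 14443008, minus strand, miR169b-5p on chromosome 5, 8527511 to 8527531, plus strand and miR864-5p on chromosome 1, 6740503 to 6740523, plus strand, each in its own MIR gene with no coding gene annotated across it. The sequence of miR169b-5p is also that of miR169c.

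**Figure D1:**
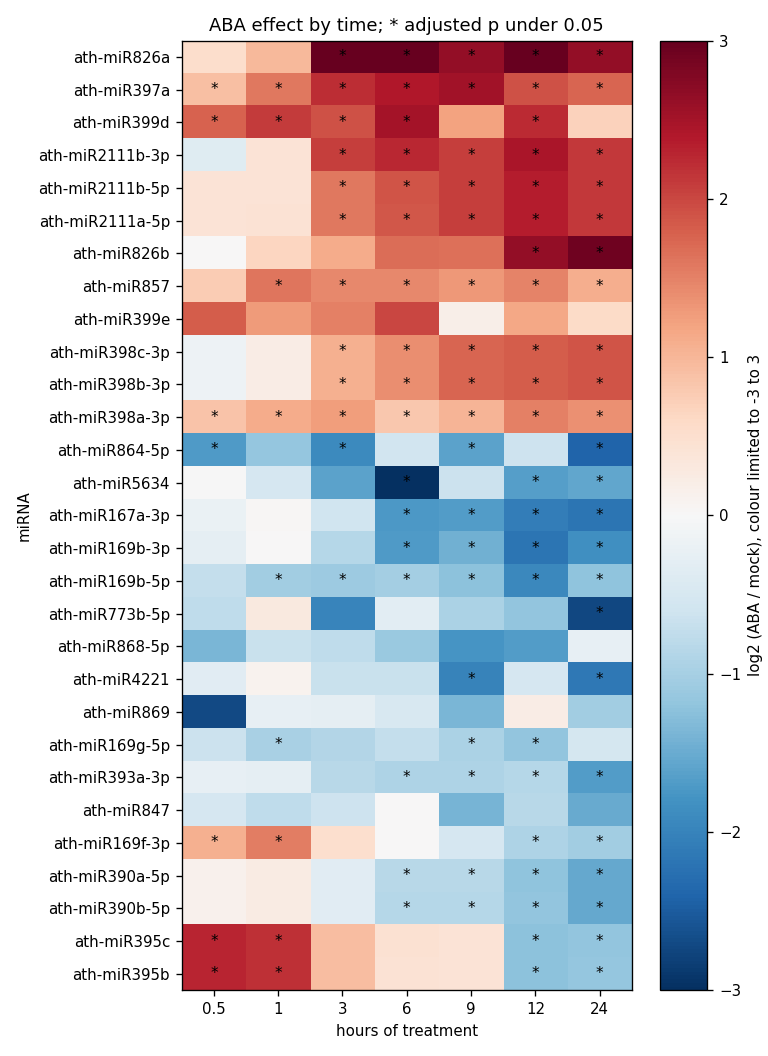
Log2 difference between ABA and mock (colour) for 29 miRNAs (vertical axis) at 7 times in hours (horizontal axis), with an asterisk where the adjusted p is under 0.05. The miR395 members are high at 0.5 and 1 h and low at 24 h, while miR397a is high at all 7 times.

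The lists fixed before the data were examined were read for the same mean contrast. In the copper list (miR397, miR398, miR408 and miR857, which target copper proteins), 6 of 7 tested members rose and 1 fell, and the counts adjusted over the list alone were the same, 6 and 1. Besides miR397a, miR857 and the miR398 3p arms, miR408-3p rose by 0.97 (SE 0.09), and miR398a-5p fell by 0.50. In the phosphate list (miR399, miR778, miR827 and miR2111), 6 of 13 tested members rose, 0 fell and 7 did not pass, and 7 rose when adjusted over the list alone. The levels of miR399d, miR399e and miR399f rose by 1.78, 1.22 and 0.63, while miR827 at 0.26 (adjusted p = 0.0734) and miR778 at -0.08 did not pass. The 6 members of the miR395 family, the whole sulfate list, target ATP sulfurylases and a sulfate transporter, and all 6 rose, also when adjusted over the list alone, by 0.55 to 0.72. They hold only 2 distinct sequences, and this mean covers both directions, with a median over members of 2.14 at 0.5 h and -1.06 at 24 h, where 3 of 6 fell. In the limma fit of the 7 ratios of means in the authors' deposited table, 0 of 6 passed (miR395c at 0.58, adjusted p = 0.327).

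In the NF-Y list, the miR169 family, 11 of 16 tested members fell, 1 rose and 4 did not pass, the same counts as adjusted over the list alone. The levels of miR169b-5p, miR169f-5p and miR169g-5p fell by 1.17, 0.79 and 0.84, and the loci h to n, which share 1 sequence, fell by 0.52 to 0.68. The levels listed for miR169d and miR169e were at 0.20 (adjusted p = 0.223 and 0.228), although they share their mature sequence with miR169f-5p and miR169g-5p, and values listed for these 4 loci differed up to 4.11-fold within a group. The member that rose was miR169g-3p at 0.31, and miR169a-3p at -0.15 and miR169f-3p at 0.09 did not pass. Among families reported elsewhere as lowered by ABA or drought (miR169, miR842 and miR846), 12 of 19 tested members fell, 1 rose and 6 did not pass, the same as adjusted over the list alone. The level of miR846-3p fell by 0.42, while miR842 was at -0.14 and miR846-5p at 0.14 without passing.

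Among families reported elsewhere as raised by ABA (miR159, miR168, miR393, miR394, miR397 and miR402), 2 of 11 tested members rose, 2 fell and 7 did not pass, the same counts as adjusted over the list alone. The risen members were miR397a and miR168b-3p at 0.46 (SE 0.13). The fallen members were the 3p arms miR393a-3p at -0.81 and miR393b-3p at -0.50. The 5p arm, an identical sequence from MIR393a and MIR393b that targets auxin receptors, had no library values. The 7 log2 ratios of its means in the authors' deposited table, fitted with limma, gave 0.84 (SE 0.14, adjusted p = 0.00169), above 0 at 7 of 7 times. Members that did not pass were miR159b-5p at 0.09, miR159c at 0.29, miR168a-3p at -0.13, miR394a at -0.11, miR394b-5p at -0.10, miR394b-3p at -0.07 and miR402 at -0.24. In the same fit of the authors' deposited table, miR159a, miR159b-3p, miR168a-5p and miR168b-5p gave 0.17, 0.17, 0.25 and 0.25, none past the threshold, miR169a-5p gave 0.19 (adjusted p = 0.333) and miR169c fell by 1.12 (adjusted p = 0.000431).

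In the auxin list (miR160, miR164, miR167, miR390 and miR393), 4 of 16 tested members rose, 8 fell and 4 did not pass, and these were also the counts adjusted over the list alone. The limma fit of the 7 ratios of deposited means covered all 24 members, of which 6 rose and 7 fell. Its median log2 ratio was 0.0004, against a median of -0.30 for the 16 tested members. The level of miR167c-3p rose by 0.77, and miR160a-3p and miR390a-5p fell by 0.72 and 0.63. In the tasiRNA list (miR173, miR390 and miR828), 4 of 6 fell, among them miR828 at -0.56, 1 rose, miR390b-3p at 0.29, and 1 did not pass, as adjusted over the list alone. In the leaf list (miR165, miR166, miR319 and miR396), 4 of 5 tested members rose, among them miR166e-5p at 0.58 and miR165a-5p at 0.33, and miR396b-3p fell by 0.46, as adjusted over the list alone. Only these 5 of the 20 members were tested. In the limma fit of the 7 ratios of deposited means over all 20, 3 rose and 0 fell, with a median log2 ratio of 0.05, so a rise of the whole list is not shown. In the silencing list (miR162, miR168 and miR403), 5 of 7 tested members rose and 2 did not pass, also adjusted over the list alone. Of these 5, 4 were miR162 members with 2 distinct sequences, and miR162b-5p at 0.61 and miR162a-5p at 0.50 share 1 of them. In the limma fit of the 7 ratios of deposited means over all 10 members, 2 rose and 1 fell. In the phase change list (miR156, miR157 and miR172), 1 of 16 rose, miR156d-3p at 0.32, and 4 fell, all of the miR172 family, such as miR172a at -0.51, again as adjusted over the list alone. In the defence list (miR472, miR482, miR825 and miR863), 2 of 5 fell, miR863-3p at -0.52 and miR863-5p at -0.19, and 3 fell when adjusted over the list alone. In the SCARECROW-LIKE list (miR170 and miR171), 1 of 8 rose, miR171c-5p at 0.58, and 2 fell, miR171a-3p at -0.29 and miR171b-5p at -0.25. In the MYB list (miR159, miR319, miR828 and miR858), 1 of 4 fell, miR828, and 3 did not pass. Both gave the same counts adjusted over the list alone.

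Of 96 tested members of conserved families, 30 rose, 30 fell and 36 did not pass, and 31 rose and 30 fell when adjusted over the list alone. Of 37 tested passenger arms, read as a sign of processing or RNA quality, 13 rose and 12 fell, also adjusted over the list alone, and their adjusted p was 0.998. The stomatal lineage list, the miR824 family, had no tested member. The limma camera test with an estimated correlation called 0 of 16 lists, and 3 lists had an unadjusted p under 0.05. A preset correlation of 0.01 called 7 lists, and none of the 7 held with an estimated correlation. With an estimated correlation the adjusted p was 0.0857 for copper, 0.0857 for phosphate, 0.395 for sulfate, 0.403 for NF-Y, 0.403 for the families reported as lowered, 0.214 for leaf and 0.214 for tasiRNA. The corresponding preset values were 5.29e-05, 0.000186, 0.00302, 0.00145, 0.00178, 0.0388 and 0.0316. With 1 miRNA for each sequence, copper alone was called. For the 11 tested members of the families reported as raised, the median log2 difference was -0.10 and the mean 0.07, with an adjusted p of 0.998 upward. Over all 18 members, the limma fit of the 7 ratios of deposited means gave a median of 0.17, with 5 raised and 2 lowered. The sign of the median thus depended on the members covered. The adjusted p was 0.465 for auxin, 0.226 for silencing, 0.863 for phase change, 0.465 for defence, 0.998 for SCARECROW-LIKE, 0.998 for MYB and 0.902 for conserved families.

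At 0.5 h after the start, the question was which miRNAs ABA changed first. Among the miRNAs named at this time, a sequence of the miR395 family rose most. The shared sequence of miR395b, miR395c and miR395f was 4.84-fold higher (log2 difference 2.27, SE 0.37, adjusted p = 0.00048), and all 6 tested members passed. Passenger arms rose in 9 of 40 tested cases and fell in 0, with miR169g-3p at 1.56 and miR396b-3p at 1.35, while miR397a was at 0.91. The lowered miRNAs were led by miR864-5p at -1.69 (SE 0.41), miR8170-3p at -1.29 and miR860 at -0.92. In all, 26 of 366 tested miRNAs passed, 20 raised and 6 lowered, and with only the 4 libraries of 0.5 h 53 of 342 passed, 28 raised and 25 lowered. The authors' deposited table called 46, 24 of them among the 26 and in the same direction, and 7 of its 46 were not tested here. Median centring moved the median of all miRNAs by 0.10 and gave 37 raised and 4 lowered, and quantile normalization gave 23 and 20. The count was 10 without mock library a, 15 without mock library b, 11 without ABA library a and 13 without ABA library b, and with 1 library out miR864-5p, miR8170-3p and miR860 lost their calls in 3, 3 and 2 of the 4 fits.

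At 1 h the same early pattern was read again. The sequence of miR395b, miR395c and miR395f was 4.57-fold higher (log2 difference 2.19, SE 0.37, adjusted p = 0.000629), and all 6 members of the miR395 family passed. The levels of miR399d, miR857, miR397a and miR398a-3p rose by 2.10, 1.59, 1.58 and 1.11, and 5 of 10 tested copper members passed. Passenger arms rose in 11 of 43 tested cases and fell in 1. The largest falls were those of miR3440b-5p at -1.94 (SE 0.54), miR1888a at -1.14 and miR860 at -1.11. Of 373 tested miRNAs, 36 passed, 26 raised and 10 lowered, and all 19 calls of the authors' deposited table were among them in the same direction. Median centring gave 27 raised and 5 lowered, and quantile normalization gave 21 and 15. The count was 21 without mock library a, 15 without mock library b and 18 without ABA library b, and miR1888a and miR3440b-5p each lost their call in 3 of the 4 fits with 1 library out.

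At 3 h the raised miRNAs included copper and phosphate ones, behind miR826a. The level of miR826a was higher by 3.05 (SE 0.67), that of miR397a was 4.61-fold higher (log2 difference 2.21, SE 0.26, adjusted p = 7.07e-06) and that of miR2111b-3p was 4.22-fold higher (log2 difference 2.08, SE 0.22). In the copper list 6 of 7 tested members rose and 1 fell, and in the phosphate list 4 of 13 rose. The largest falls were those of miR864-5p at -1.91, miR171b-5p at -1.22 and miR169b-5p at -1.08. Of 356 tested miRNAs, 23 passed, 14 raised and 9 lowered, where the authors' deposited table called 1. Quantile normalization gave 14 raised and 3 lowered, median centring gave 14 and 5, and joint scaling over all libraries also left 73.7% raised. With only the 4 libraries of 3 h, 5 passed, and miR826a, miR864-5p, miR171b-5p and miR169b-5p did not, with the same log2 differences and larger SEs (0.84 for miR826a). The count was 36 without mock library a (17 raised, 19 lowered), 9 without mock library b and 6 without ABA library b, and each of these 4 miRNAs lost its call in 1 or 2 of the 4 fits with 1 library out.

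At 6 h the raised miRNAs again included copper and phosphate ones, behind miR826a. The level of miR397a was 5.3-fold higher (log2 difference 2.41, SE 0.26, adjusted p = 1.82e-06), that of miR399d 5.66-fold higher (log2 difference 2.50, SE 0.44) and that of miR826a was higher by 3.38 (SE 0.67). In the copper list 9 of 10 tested members rose and 1 fell. The level of miR5634 was 8.1-fold lower (log2 difference -3.02, SE 0.53), and miR167a-3p and miR169b-3p fell by 1.73 and 1.70. Of 377 tested miRNAs, 34 passed, 16 raised and 18 lowered. Of the 16 calls of the authors' deposited table, 15 were among them in the same direction and 1 was not tested here. With only the 4 libraries of 6 h the count was 19, 12 raised and 7 lowered. It was 14 without mock library a (6 raised, 8 lowered), 18 without mock library b (14 and 4) and 15 without ABA library b (11 and 4), so the balance of directions depended on the libraries, and miR826a lost its call in 2 of the 4 fits, miR167a-3p without ABA library b and miR169b-3p without mock library b.

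At 9 h miR408-5p, the partner of the copper miRNA miR408-3p, was 6.76-fold higher (log2 difference 2.76, SE 0.28, adjusted p = 9.92e-07). The levels of miR826a and miR397a were higher by 2.64 (SE 0.67) and 2.53 (SE 0.26), and 7 of 8 tested copper members passed. The largest falls were those of miR4221, 4-fold lower, miR167a-3p at -1.67 and miR864-5p at -1.60. In the miR169 family, 5 of 17 tested members fell and 0 rose. Of 367 tested miRNAs, 49 passed, 26 raised and 23 lowered. The authors' deposited table called 22, 15 of them among the 49 and in the same direction, and 4 of its 22 were not tested here. With only the 4 libraries of 9 h miR826a did not pass, at the same log2 difference (SE 1.07, adjusted p = 0.0843). The count was 29 without mock library a, 30 without mock library b and 15 without ABA library a, and with 1 library out miR864-5p lost its call in 3 of the 4 fits, miR4221 and miR826a in 2 and miR167a-3p without ABA library a.

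At 12 h miR2111b-3p was 5.49-fold higher (log2 difference 2.46, SE 0.22, adjusted p = 1.11e-07), and miR826a and miR826b were higher by 3.75 (SE 0.67) and 2.63 (SE 0.75). In the copper list 7 of 8 tested members rose, with miR397a at 1.91 and miR398b-3p at 1.81. The level of miR169b-3p was 4.55-fold lower (log2 difference -2.19, SE 0.35), and miR167a-3p and miR169b-5p fell by 2.08 and 1.92. The sequence of miR395b, miR395c and miR395f, raised at 0.5 and 1 h, fell by 1.23 (SE 0.37, adjusted p = 0.0367), and the other miR395 sequence was at -0.02 without passing. Of 362 tested miRNAs, 40 passed, 25 raised and 15 lowered. With only the 4 libraries of 12 h the count was 98 of 344, 48 raised and 50 lowered. The authors' deposited table called 98 of 409, 38 of them among the 40 and in the same direction, and 20 of its 98 were not tested here. The count was 18 without mock library a, 23 without mock library b, 24 without ABA library a and 18 without ABA library b, and miR826b lost its call in 3 of these fits, and with a pseudocount of 0.1 its log2 difference was larger, 4.42 (SE 1.73), but did not pass (adjusted p = 0.115).

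At 24 h 79 of 373 tested miRNAs passed, 39 raised and 40 lowered. This was the highest count of the 7 times in the fit of all libraries, while with only the 4 libraries of each time 76 passed at 24 h and 98 at 12 h. The level of miR2111b-3p was 4.36-fold higher (log2 difference 2.13, SE 0.22, adjusted p = 1.38e-06), and miR826b and miR826a were higher by 2.92 (SE 0.75) and 2.64 (SE 0.67). In the copper list 7 of 8 tested members rose, with miR398b-3p at 1.89. The level of miR391-3p was 7.54-fold lower than in mock (log2 difference -2.91, SE 0.57), and miR773b-5p and miR864-5p fell by 2.73 and 2.41. In mock alone miR391-3p changed with time (F test of the mock course, F = 8.88, adjusted p = 0.0047) and was higher at 24 h than at 0.5 h. Its difference at 24 h therefore does not show a fall from the start under ABA. The sequence of miR390a-5p and miR390b-5p, a trigger of tasiRNA production, fell by 1.53 (SE 0.17), and passenger arms fell in 12 of 39 tested cases and rose in 3. The sequence of miR395b, miR395c and miR395f fell by 1.16, while that of miR395a, miR395d and miR395e was at -0.97 (adjusted p = 0.0581). The authors' deposited table called 63 at this time, 48 of them among the 79 and in the same direction, and 8 of its 63 were not tested here. The count was 32 without mock library a (16 raised, 16 lowered), 42 without mock library b (23 and 19) and 36 without ABA library b (18 and 18), and with 1 library out miR773b-5p, miR826a and miR826b each lost their call in 2 of the 4 fits, miR826a also with a pseudocount of 0.1, at 3.07 (SE 1.42, adjusted p = 0.124).

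Across times, the adjusted p of the authors' deposited table was under 0.05 for 136 miRNAs at any time, for 17 at 4 or more times, and in both directions for 10. The authors' deposited table called 98 miRNAs at 12 h and 1 at 3 h. Its number of calls was lower where the libraries of a group differed more: over the 7 times, Pearson's r with the mean SD of the log2 difference between libraries was -0.953 (exact permutation p = 0.00198, two-sided) and Spearman's rho was -0.857 (exact permutation p = 0.0238). Without 3 and 12 h, r was -0.882.

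**Figure D2:**
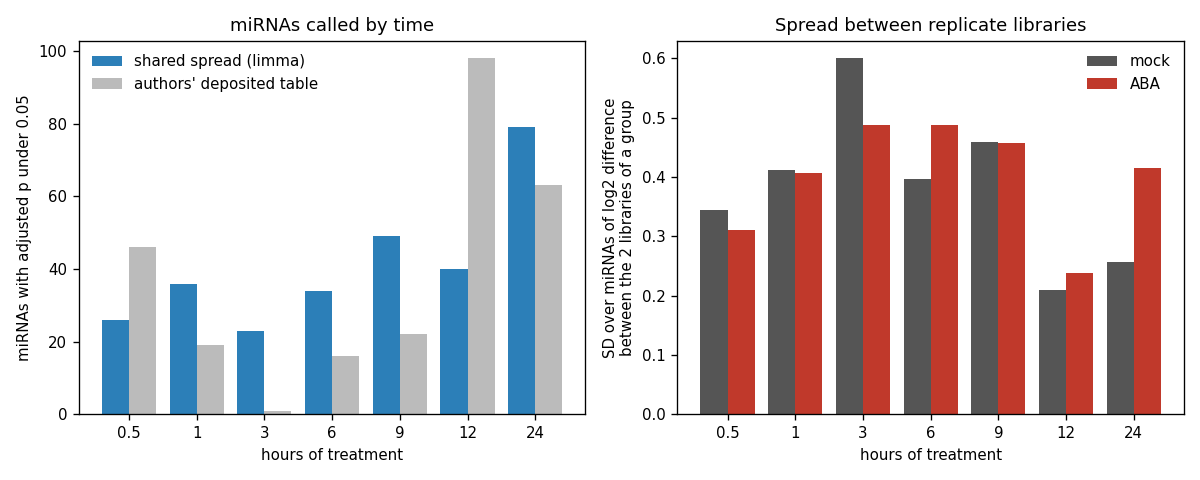
Number of miRNAs past an adjusted p of 0.05 at each time in hours, here and in the authors' deposited table, beside the SD of the log2 difference between the 2 libraries of each group. The deposited calls are most at 12 h, 98, where the libraries of both groups lie closest.

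The next comparison asked whether the ABA effect changed with time, as the mean effect at 6, 9, 12 and 24 h minus that at 0.5, 1 and 3 h. The effect on the miR395 family was lower at the late times: the difference was -2.19 for miR395c (SE 0.28, adjusted p = 1.09e-05) and -1.24 for each of miR395a, miR395d and miR395e. The effect on miR2111b-3p grew by 1.53 (SE 0.16, adjusted p = 3.72e-06). The effect on miR169f-3p differed by -1.66 (SE 0.20) and those on miR390a-5p and miR390b-5p by -1.11 and -1.12. Within each time, the mean normalised read count of miR395b was 1753 ± 106 in ABA against 364 ± 56.2 in mock at 0.5 h, and 167 ± 4.7 against 375 ± 1.2 at 24 h (SD, n = 2 libraries each). For miR169f-3p it was 6429.8 ± 1437 against 2206 ± 492 at 1 h and 1037 ± 2.33 against 2151 ± 188 at 24 h (SD, n = 2).

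Of 355 tested miRNAs, 58 passed, 22 with a higher and 36 with a lower late effect, and 44 of the 58 also passed the mean contrast. Median centring gave 11 and 41, and quantile normalization gave 33 and 35. The count was 35 without 0.5 h, 30 without 1 h, 25 without 24 h, 37 without mock library a of 0.5 h and 36 without mock library b of 1 h. Fitted to the 7 ratios of means, 23 of 407 passed, and miR2111b-3p (1.52, adjusted p = 0.074) and miR395a (-1.20, adjusted p = 0.124) did not. The F test of any difference in ABA effect between times called 23 of 355, led by miR2111b-3p (F = 25.9, adjusted p = 6.53e-06), miR169f-3p (F = 15), miR390a-5p (F = 14.7), miR395c and miR395b (F = 14.6 each). When treatment labels were shuffled within times, 5 of 100 splits, the real one included, gave as many calls by this F test. The mature miR395b lies on chromosome 1, 9364540 to 9364560, plus strand, miR390a-5p on chromosome 2, 16061971 to 16061991, plus strand and miR169f-3p on chromosome 3, 4805713 to 4805733, minus strand, each in its own MIR gene.

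**Figure D3:**
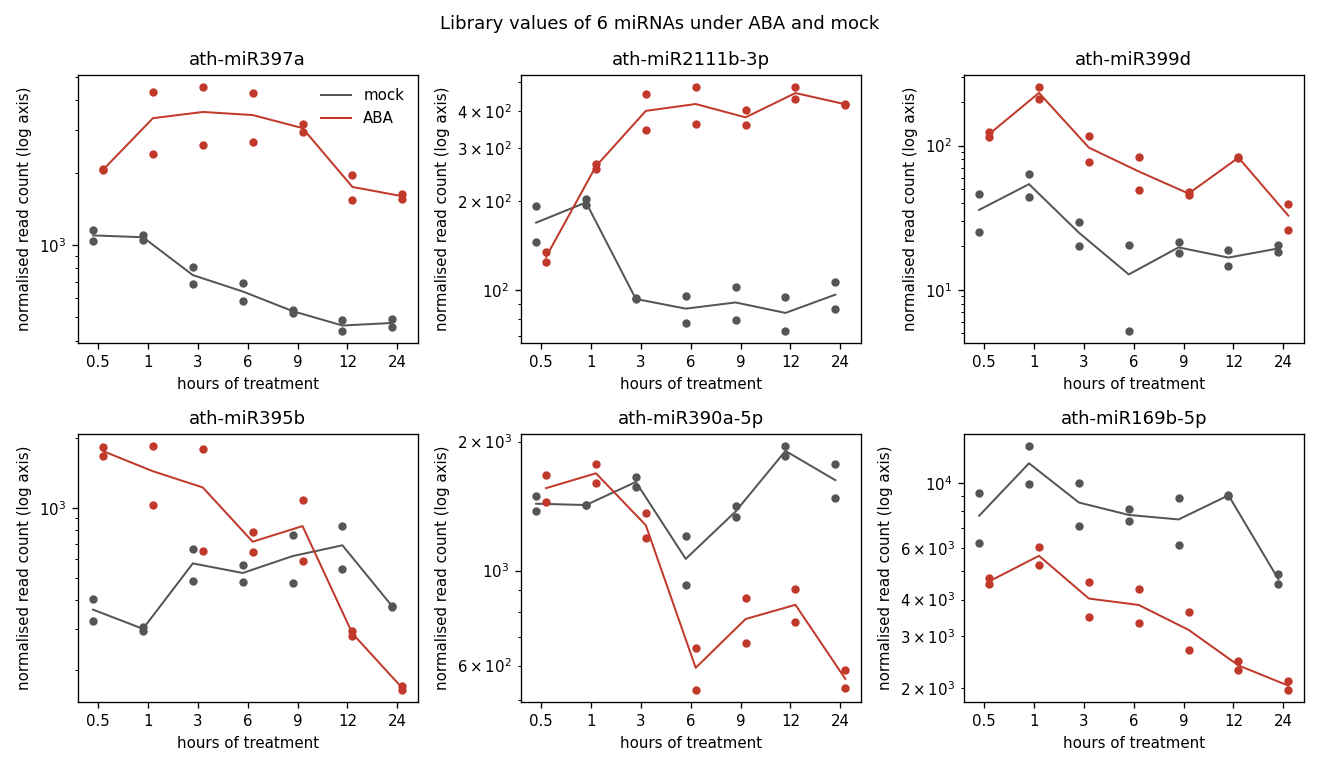
Normalised read count (log axis) of 6 miRNAs against time in hours for ABA and mock. Values keep the authors' separate scaling of each time, so ABA and mock can be compared within a time but levels cannot be compared between times. Points are the 2 recovered libraries of each group and lines their mean; for miR395b the ABA line starts above mock, 1753 against 364 at 0.5 h, and ends below it, 167 against 375 at 24 h.

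The last comparisons asked which miRNAs changed with time in mock alone and in ABA alone, on values scaled jointly over the 28 libraries, where the hour of treatment and of the day cannot be separated. In mock, the level of miR5651 went from 256 ± 13.2 at 0.5 h to 742 ± 49.3 at 24 h and that of miR391-3p from 22.8 ± 1.08 to 195 ± 29.9 (SD, n = 2 libraries each). The level of miR164b-3p went from 218 ± 46 at 0.5 h to 63.7 ± 12.5 at 3 h and that of miR398b-3p, whose sequence is also that of miR398c-3p, from 4253 ± 981 at 0.5 h to 1426 ± 320.0 at 9 h (SD, n = 2). The F test called 57 of 360 tested miRNAs in mock, led by miR5651 (F = 10.7, adjusted p = 0.0047), miR164b-3p, miR398c-3p, miR398b-3p, miR166e-5p, miR391-3p, miR846-5p and miR157c-3p (F = 7.04). In ABA it called 53 of 359, led by miR169f-3p (F = 23.8, adjusted p = 8.74e-06), miR2111b-3p, miR395c, miR395b, miR395f, miR390b-5p, miR390a-5p and miR169g-3p (F = 14.4). In ABA the level of miR2111b-3p went from 125 ± 7.26 at 0.5 h to 459 ± 24.1 at 24 h and that of miR395b from 1692 ± 116 to 182 ± 13.8 (SD, n = 2). Both courses called 14 miRNAs in common.

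On the authors' scaling within each time, the counts were 85 in mock and 97 in ABA, and quantile normalization gave 21 in mock. The mock count was 7 and 17 without mock library a or b of 24 h, 22 and 15 without mock library a or b of 12 h, 25 and 16 without mock library a or b of 1 h, 25 without either mock library of 0.5 h and 30 without mock library b of 9 h. It was 35 without either ABA library of 0.5 h and 37 without either ABA library of 12 h.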

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

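The tests of other splits of the libraries, of the authors' 12 h calls, of the miR395 effect, the passenger arms beside it, and of the miR393 arms were chosen only after the results were seen, while the interaction and late minus early tests were fixed before. In all, 32 miRNAs stood out because their ABA effect differed between times by a test of the difference itself, 23 by the interaction F test and 9 further named ones by the late minus early contrast. The 23 held only 16 distinct mature sequences. Values are the log2 ABA effect at 6 to 24 h minus that at 0.5 to 3 h. Higher late effects came with miR2111b-3p at 1.53, miR2111b-5p at 1.30, miR2111a-5p at 1.29, miR398b-3p and miR398c-3p at 1.33 each, and miR164b-3p at 0.41. The miR395 family gave -2.19 for miR395c, -2.18 for miR395b, -2.16 for miR395f and -1.24 for each of miR395a, miR395d and miR395e. In the miR169 family only 3 of 16 tested members passed late minus early, all of them 3p arms. These were miR169f-3p at -1.66, miR169g-3p at -1.31 and miR169b-3p at -1.41. Lower late effects came also with miR390a-5p at -1.11, miR390b-5p at -1.12, miR396b-3p at -1.27, miR399c-5p at -1.25 and miR167a-3p at -1.67. The same held for miR157c-3p at -1.35, miR5028 at -0.99 and miR447c-5p at -2.26. Of these 23, 22 also passed the late minus early contrast, and miR164b-3p did not (adjusted p = 0.232).

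Late minus early called 58 miRNAs, which held 47 distinct mature sequences, and 22 of the 58 were also called by the F test. Of those not called by the F test, the 9 named under the naming rule were miR826a at 1.59, miR397a at 0.58, miR402 at 1.09, miR860 at 0.63, miR846-5p at 0.55, miR4221 at -1.03, miR391-3p at -1.76, miR5651 at -0.76 and miR393a-3p at -0.65.

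Treatment labels were shuffled within times in 99 other splits and counted with the real labels, 100 in all, over the 355 miRNAs with values in every library. The mean contrast called 167 with the real labels and at most 26 with others, so 1 of 100 splits gave as many, the smallest share these splits can give. This argues against chance for the count as a whole, not for single miRNAs. Late minus early called 57 against at most 48, also 1 of 100. Most other splits placed ABA and mock libraries in the same group at several times. A lasting ABA effect then widens the spread within groups and lowers the counts of these splits. They therefore cannot exclude chance for late minus early. The interaction called 24 with the real labels and up to 96 with others, and 5 of 100 splits gave as many, so chance cannot be excluded for that count. Each of the 4 other splits as large kept or swapped whole treatments at 4 or more times, where the median over all splits was 2, and swapping a whole time turns a lasting ABA effect into a difference between times.

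Late minus early for the miR395 family was below 0 with an adjusted p under 0.05 in 18 of 18 fits of the 6 members under 3 other scalings, at -2.27 to -1.02, which argues against library scaling as the cause. It was below 0 in every fit of the 6 members with 1 library left out, at -2.43 to -1.07. The largest adjusted p of these fits was 0.0108, which argues against 1 library. Both of the 2 distinct mature sequences passed, which cannot decide on 1 set of reads counted at 6 copies, since both would then pass. Such copies would give equal values, but miR395c of 1 sequence was at -2.19 and the other sequence at -1.24. These sizes argue against 1 set counted alike at all 6 loci. Reads shared in part between the sequences stay open, as the handling of reads that map to several loci is not given. An hour of the day that acts alike in both treatments cancels by design in the ABA minus mock difference of each time, and no further test of it was run. Processing or RNA quality cannot be told apart from a response to ABA, since 7 of 33 passenger arms, 1 per sequence, had a late minus early as low as the weakest member at -1.24, although the passenger median was -0.38 (SD 0.66). An ABA response that depends on the hour stays open, as the labels give no clock hour, and so does a change of the response with time under ABA.

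The 5p arm shared by MIR393a and MIR393b was higher under ABA by 0.84, and the 3p arm of MIR393a gave -0.80, both as log2 ratios of means in the authors' deposited table averaged over 7 times. If the shared sequence stood for MIR393b while MIR393a fell, the 3p arm of MIR393b was predicted to be at 0 or higher. In the limma fit of these ratios it was at -0.48 (SE 0.12, adjusted p = 0.0129). This cannot decide, since a 3p arm need not follow its precursor: late effects of the 2 arms had opposite signs in 14 of 42 precursors. MIR393b as the source of the 5p rise therefore stays open. The difference between the arms, 1.64 (SE 0.30), lay above 0 at 7 of 7 times, from 0.32 to 2.69, and no factor per library can change it, which argues against scaling. Unequal retention of the arms under ABA may account for it, and how reads that map to both loci were counted stays open, as neither was tested.

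The authors' deposited table called the most miRNAs at 12 h, 98, and the fewest at 3 h, 1. With 1 spread shared by all times, 12 h had 40 calls and 24 h had 79, so closer libraries at 12 h may account for its place at the top of the deposited order. Of the 98 deposited calls, 20 were not tested here, which also lowers the count at 12 h. At 3 h there were 23 calls, still the fewest, so the shared spread did not change the low end of the order. The variance of effects net of replicate error was also lowest at 3 h, 0.219 (SE 0.045). Whether the ABA effect itself was widest at 12 h cannot be told apart from closer libraries there. The SD of effects over miRNAs net of replicate error was 0.694 at 12 h and 0.750 at 24 h, and the difference of their variances was -0.0818 (SE 0.104), within its error.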

How the results depend on the processing

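The other scaling across times, 1 miRNA per sequence, the ratios of deposited means, the deposited p-value as call and leaving out a time were chosen after seeing the data. No paired analysis was possible because the recovered libraries carry no replicate number, and for the same reason the replicate block was not run, nor were count tools. No direction of a named miRNA reversed in 1726 refits of 71 named results, and 76 refits, 62 of them with 1 library out, lost the call. The absence of reversals cannot show robustness, since the naming rule largely fixes it. Single-time names needed the ABA libraries all above or all below the mock libraries, so leaving out 1 library could not turn their sign. Names for the mean contrast needed the same sign at most times. Fits of only the libraries of a time also left the log2 difference itself unchanged, as for miR826a at 3 h. Of the counts outside single-library refits, 101 stayed within 1.5 times and 22 moved. The full depth of the libraries is unknown, and library values cover 360 miRNAs.

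Among moved counts, the mean contrast gave 110 with ratios of deposited means, which have 7 values per miRNA. At 0.5 h the count was 43 with quantile normalization, 41 with median centring, 40 with a mean of at least 10 and 53 with only the 4 libraries of that time. That last setting gave 5 at 3 h, 19 at 6 h and 98 at 12 h. The deposited p-value called 46 at 0.5 h, 19 at 1 h, 1 at 3 h, 16 at 6 h, 22 at 9 h and 98 at 12 h. Late minus early gave 23 with ratios of means, 35 without 0.5 h, 30 without 1 h and 25 without 24 h. The mock course gave 21 with quantile normalization and the ABA course 97 with the authors' scaling. The lists gave 7 with a preset correlation, which is smaller than most estimated ones, and 1 with 1 miRNA per sequence. The cause was not tested for the others.

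With 1 library left out, its group keeps 1 library, assumed to vary like the other groups. The mean contrast then ranged from 148 to 166, the interaction from 19 to 34, the ABA course from 37 to 71 and the lists stayed at 0. At 0.5 h the range was 10 to 15, where each of mock a (10), mock b (15), ABA a (11) and ABA b (13) moved the count over 1.5 times. At 1 h it was 15 to 29, moved by mock a (21), mock b (15) and ABA b (18). At 3 h it was 6 to 36, moved by mock a (36), mock b (9) and ABA b (6). At 6 h it was 14 to 43, moved by mock a (14), mock b (18) and ABA b (15). At 9 h it was 15 to 53, moved by mock a (29), mock b (30) and ABA a (15). At 12 h it was 18 to 24, moved by mock a (18), mock b (23), ABA a (24) and ABA b (18). At 24 h it was 32 to 75, moved by mock a (32), mock b (42) and ABA b (36). Late minus early ranged from 36 to 71, moved by mock a of 0.5 h (37) and mock b of 1 h (36). The mock course ranged from 7 to 65, moved at 24 h by mock a (7) and b (17), at 12 h by mock a (22) and b (15) and ABA a and b (37 each), at 9 h by mock b (30), at 1 h by mock a (25) and b (16), and at 0.5 h by mock a and b (25 each) and ABA a and b (35 each).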

Other observations

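The fit of ratios of deposited means and the correlations between times were chosen after seeing the data, while the tests of the arms and of GC content were written before. In the limma fit of the 7 log2 ratios of means in the authors' deposited table, 407 miRNAs were tested and 110 passed, 50 raised and 60 lowered. Among the abundant miRNAs without library values in at least 1 group, those that passed included miR408-5p, raised by 1.69 (SE 0.18, adjusted p = 0.000133), miR156f-3p by 1.29, miR397b by 1.06, the shared miR398b-5p and miR398c-5p sequence by 0.95 to 2 decimals, miR167d by 0.57 and miR822-3p by 0.54. Lowered ones included miR163 at -0.99 (SE 0.18, adjusted p = 0.00298), miR158a-5p at -0.64, miR158a-3p at -0.59, miR157a-5p and miR157b-5p at -0.56, miR403-3p at -0.46 and miR173-5p, a trigger of tasiRNA production, at -0.44. The sequence of miR157a-5p and miR157b-5p is also that of miR157c-5p, and values listed for these loci differed up to 2.18-fold within a group. The single-time log2 ratios ran from -0.94 to 0.26 for miR157a-5p and from -0.61 to 0.62 for miR157c-5p. The stomatal lineage miRNA miR824-5p, which targets AGL16, had a mean log2 ratio of 0.44 (adjusted p = 0.207), and its late minus early difference was 1.32 (adjusted p = 0.0258).

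Across 143 miRNAs, 1 for each sequence, which are not independent replicates, the ABA effects correlated between most times: 18 of 21 pairs passed by Pearson's r and 19 by Spearman's rho at an adjusted p under 0.05. The r was 0.730 between 0.5 and 1 h (Spearman's rho 0.648) and 0.886 between 12 and 24 h (rho 0.841), with a permutation p of 0.0001, the smallest they can give, and an adjusted p of 0.0002 for each. Between 0.5 and 24 h, r was -0.00823 (permutation p = 0.918, adjusted p = 0.918) and rho was 0.111 (permutation p = 0.1845, adjusted p = 0.1845). The order did not follow the distance in time throughout, as r was 0.805 between 6 and 24 h, and it was 0.298 between 0.5 and 9 h against 0.106 between 0.5 and 6 h (adjusted p = 0.0006 and 0.2348).

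A hypothesis was that both arms of a precursor follow its level. Over 42 precursors with both arms at a mean of at least 100, Spearman's rho between the late ABA effects of the 5p and 3p arms was 0.523 (permutation p = 0.0005), and Pearson's r was 0.683 (permutation p = 1e-05, the smallest they can give) and 0.567 without the 2 farthest precursors. The arms had opposite signs in 14 of 42 precursors, so the values may hold a shared part for many precursors and not for all. Several arms, such as miR166a-3p, miR168a-5p and miR393b-5p, have a sequence shared with other loci and cannot be assigned to 1 precursor. For these the comparison is not within a single precursor. A further hypothesis was a bias with GC content of the mature sequence: over 294 sequences, Spearman's rho between GC percent and the mean ABA effect was 0.221 (permutation p = 0.00014). This is a weak relation, close to the 0.2 set before as the smallest that counts, and GC bias of the libraries may contribute to it, as may the composition of the families that responded.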
